A study of Homo sapiens with 12 samples.

How the data were processed

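Polyadenylated RNA was sequenced in 12 libraries of the prostate cancer cell lines PC3 and 22Rv1. Each line was infected with a lentivirus carrying eGFP, wild-type ETV4 with eGFP or mutated ETV4 (ETV4AAA) with eGFP, and eGFP-positive, DAPI-negative cells were sorted after 1 week, per the labels. There are 6 groups of 2 libraries. Per the submitters' processing notes, reads from a NextSeq 500 were checked with FastQC 0.11.9 and aligned with STAR 2.5.3a to GRCh38. The counting program, the strand setting and the annotation release are not given in the sources used here. The deposited table holds raw counts per Ensembl gene, 58302 genes in 12 columns, and the values are whole numbers with a different total in each library. Every column was matched to a library by cell line, construct and replicate number. The labels also describe single-cell and deeper sequencing, which these samples do not hold.

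Gene IDs were matched to GENCODE 29, which holds 99.55% of them. No ID occurs more than once, and 1289 IDs carry a symbol that another ID also carries. Symbols, positions and gene types come from that release, which may not be the one the submitters counted with. Reads of near-identical genes such as HSPA1A and HSPA1B, or of a gene and its antisense neighbour, may be assigned to either, since the strand setting is not known.

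Counts were analysed in R 4.3.3. Genes were filtered with filterByExpr by group, which kept 23238, and scaled with TMM factors. A quasi-likelihood negative binomial model with 1 mean per group was fitted to all 12 libraries with edgeR 4.0.16. In each line ETV4WT and ETV4AAA were tested against eGFP and against each other, 6 comparisons in all, and the 3 effects were tested for a difference between 22Rv1 and PC3 by interaction contrasts. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The standard error of a log2 change is its size divided by the square root of the F statistic. For a group with 0 to 3 counts it can be far too small. The biological coefficient of variation was 0.149 with 6 residual degrees of freedom. The replicate number was not used as a block, because the labels do not say that it marks a shared culture or day. CPM values use library sizes scaled by TMM. For a group with 0 counts the fold is a lower bound against a floor of 3 counts over the group, and for 1 to 3 counts a ratio of pooled counts with a 95% interval is given. Reads were amplified and carry no molecular identifiers, so these intervals hold counting error alone.

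Gene lists were tested with camera from limma 3.58.1, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over 144 tests, and over 72 tests for the differences between lines. Of 24 lists, those reported are ERK pathway output, reported PEA3 factor targets, p53 targets, senescence and secretory genes, mesenchymal, epithelial, cell cycle, prostate luminal, prostate basal, neuroendocrine, interferon, NF-kB, TGF-beta, amino acid and endoplasmic reticulum stress, sterol synthesis, hypoxia and glycolysis, immediate early and heat shock, ribosomal protein, mitochondrial, immune cell, and stromal and endothelial genes, with markers of 22Rv1 low in PC3 and markers of PC3 low in 22Rv1. Some lists share genes, for example 7 between the senescence and NF-kB lists. The filter removed members of some lists, and 6 of 18 immune cell genes were tested. Rises and falls are counted at an adjusted p under 0.05 over all genes, and again with p adjusted over the list alone.

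Named genes follow a rule. ETV4, ETV1 and ETV5 are always eligible. For a construct against eGFP the 8 largest rises and 8 largest falls are eligible, and for the other contrasts the 5 largest of each, among genes past the threshold with non-overlapping libraries, a mean of at least 5 CPM in a group and an official symbol. Y-linked genes and XIST were excluded. From each list up to 4 called members with the lowest adjusted p and up to 1 uncalled member with the highest CPM are eligible, and a selection of eligible genes is named. In addition, 1 list, which stays in the adjustment and in the totals of list calls, some eligible genes and the tests that rest on them are not reported here. The groups, the comparisons, the tests, the lists, the naming rule and the alternatives were fixed before the data were examined, except where the text says otherwise.

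Calls shared between comparisons were set against the number that independent calls would give, and across lines tested with a one-sided Fisher's exact test. The same test of opposite calls was added after seeing the data. For comparisons that share eGFP libraries, 20 simulations of unchanged groups with a shared control gave the number and covariance to set beside the observed values. The alternatives were DESeq2 size factors, upper-quartile factors, no low-count filter, the Wald test of DESeq2 1.42.0, limma-voom, each line fitted on its own, only the 4 libraries compared, a replicate block, an added 2-fold threshold, and leaving out each library in turn. With 1 library left out, the lone library of a group is assumed to vary like those of the other groups. Lists were also tested with an estimated correlation and with fry. Alternatives chosen after seeing the data were a floor of 1 CPM within the line and leaving out both PC3 replicate 2 libraries with a construct.

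A gene at 1 CPM has 41.7 to 51.2 counts in a library before scaling. The model was tested on simulated data with 22045 genes. In 4 simulated comparisons, edgeR recovered 100% of genes changed 4-fold and 72%, 74%, 72% and 62% of genes changed 2-fold, and 6%, 9.4%, 7% and 7.4% of its calls were unchanged genes. Of 200 unchanged simulated lists 2% had an unadjusted p under 0.05, and 100% of 20 shifted lists were found. Simulated genes were independent, so this does not test the preset correlation. Other splits of the samples were not counted, because each group holds 2 libraries.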

Results

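The data are counts of polyadenylated RNA in 12 libraries of 2 human prostate cancer cell lines. PC3 is a line from a bone metastasis that lacks p53. 22Rv1 derives from the CWR22 xenograft and expresses luminal prostate genes. Cells carried a lentivirus with eGFP alone, wild-type ETV4 and eGFP (ETV4WT) or mutated ETV4 and eGFP (ETV4AAA), and were sorted 1 week after infection. Which residues differ in ETV4AAA is not given in the sources used here. Each of the 6 groups holds n = 2 libraries. ETV4 belongs to the PEA3 group of ETS transcription factors, with ETV1 and ETV5, and is activated by gene fusions in a subset of prostate tumours.

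The libraries hold 43572713 to 51199207 counts in PC3 and 41698738 to 50226044 counts in 22Rv1. Mitochondrial transcripts held 4.31% to 5.14% of the counts in PC3 and 8.05% to 9.81% in 22Rv1. The first principal component, which carried 84.7% of the variance, separated the lines. The replicate spread, as chi-square per degree of freedom against counting error, was 3.55 in PC3 eGFP and between 24.1 and 66 in the other groups. Levels below are mean CPM (library-scaled counts) ± SD, and log2 changes are ± SE, with n = 2 libraries per group. Adjusted p-values are Benjamini-Hochberg values from edgeR's quasi-likelihood test for genes and from camera for gene lists. The labels do not say whether replicates are separate cultures, so p-values measure the spread between these samples. Both libraries of one group lay beyond both libraries of the other for each gene named as risen or fallen.

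In 22Rv1 ETV4 stood at 31.2 and 24.9 CPM with eGFP, 385 and 484 CPM with ETV4WT, and 390 and 281 CPM with ETV4AAA. In PC3 it stood at 121 ± 6.61 CPM with eGFP, 215 and 112 CPM in the libraries labelled ETV4WT, and 223 and 109 CPM in the libraries labelled ETV4AAA. ETV4 was therefore above eGFP in replicate 1 of both PC3 constructs and not in replicate 2. These replicates also differed for other genes: KRT19 was 231 and 108 CPM with ETV4WT and 265 and 124 CPM with ETV4AAA, and HSPB1 91.1 and 29.9, and 124 and 39.9 CPM, so the difference is not particular to ETV4. LRRC15 was nonetheless high in both replicates, at 60.1 and 51.6 CPM in ETV4WT libraries and 68.7 and 60.1 in ETV4AAA libraries. With eGFP it was 0.0403 and 0.086 CPM. The counts do not separate endogenous from introduced ETV4 transcripts.

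**Figure D1:**
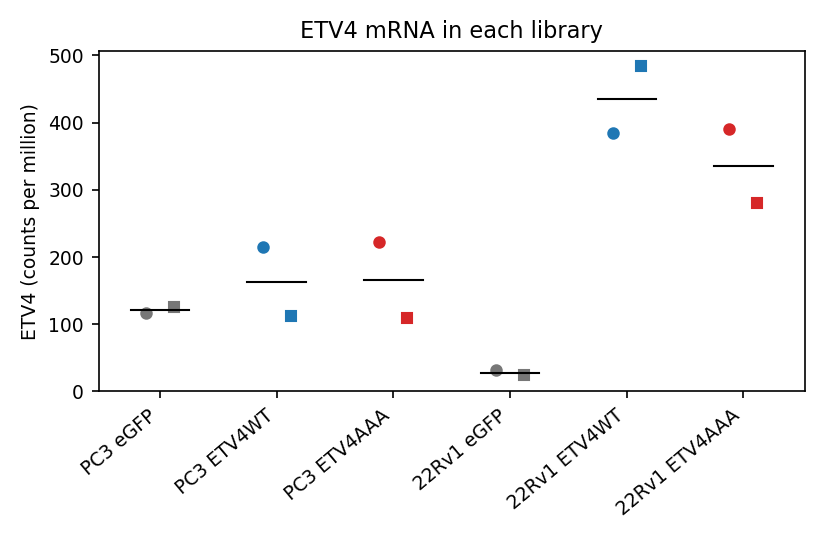
ETV4 in CPM (axis from 0) for each of the 12 libraries, grouped by cell line and construct, with points for libraries and bars for group means. In PC3 the replicate 2 libraries of ETV4WT (112) and ETV4AAA (109) lie below both eGFP libraries (mean 121).

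All of the genes located here are protein-coding in GENCODE 29, with positions on GRCh38. ETV4 (ENSG00000175832) lies on chromosome 17 from 43527844 to 43579620, ETV1 (ENSG00000006468) on chromosome 7 from 13891228 to 13991425, and ETV5 (ENSG00000244405) on chromosome 3 from 186046308 to 186110318. LRRC15 (ENSG00000172061) lies on chromosome 3 from 194355247 to 194369743, MYL10 (ENSG00000106436) on chromosome 7 from 101613325 to 101629296, and CHAC1 (ENSG00000128965) on chromosome 15 from 40952962 to 40956519. SPARC (ENSG00000113140) lies on chromosome 5 from 151661096 to 151687165, S100A9 (ENSG00000163220) on chromosome 1 from 153357854 to 153361027, and KRT75 (ENSG00000170454) on chromosome 12 from 52424070 to 52434525. DUSP6 (ENSG00000139318) lies on chromosome 12 from 89347232 to 89353271, CDKN1A (ENSG00000124762) on chromosome 6 from 36676460 to 36687339, and FAM111B (ENSG00000189057) on chromosome 11 from 59107185 to 59127410.

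The first comparison asks what ETV4WT changes in PC3. In the libraries labelled ETV4WT, 18 of 24 genes of the amino acid and endoplasmic reticulum stress list rose and 1 fell (adjusted p = 7.7e-16), and 13 of 28 interferon response genes fell and 0 rose (adjusted p = 1e-06). CHAC1, a glutathione-degrading enzyme of that stress response, rose from 2.62 ± 0.0329 to 39.9 ± 14.9 CPM, a log2 change of 3.93 ± 0.45 (adjusted p = 7.46e-05). The interferon-induced antiviral enzyme OAS1 fell from 13.1 ± 0.0926 to 2.11 ± 0.0331 CPM, a log2 change of -2.63 ± 0.25 (adjusted p = 1.73e-05). The matrix metalloproteinases MMP3 and MMP10, both in the list of reported PEA3 factor targets, rose by log2 2.61 ± 0.25 and 1.39 ± 0.20. Of 23238 genes tested, 5434 changed, 2958 up and 2476 down.

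LRRC15, a leucine-rich repeat membrane protein known from mesenchymal cells, had the largest rise by the naming rule, to 55.8 ± 6.04 CPM (log2 9.75 ± 0.36, and 10.42 without eGFP replicate 2). The prokineticin receptor PROKR1 (log2 6.31 ± 0.26), the myosin light chain MYL10 (5.41 ± 0.26), the cyclic nucleotide phosphodiesterase PDE2A (4.58 ± 0.27) and the inhibin subunit INHBE (3.91 ± 0.26, to 55.4 ± 4.07 CPM) were among the other large rises. Among the largest falls were FGFBP1, a carrier of fibroblast growth factors (-2.46 ± 0.20), the heat shock gene HSPA1A (-2.58 ± 0.26), the ligand WNT9A (-2.70 ± 0.31) and IGSF9 (-2.78 ± 0.29). ETV5 rose by log2 0.76 ± 0.12 (adjusted p = 0.000923), while ETV1 (-0.17 ± 0.13, adjusted p = 0.366) and ETV4 (0.43 ± 0.33, adjusted p = 0.384) did not pass. ETV4's log2 change was -0.12 without ETV4WT replicate 1, 0.83 without ETV4WT replicate 2, and 0.92 without both PC3 replicate 2 libraries that carry a construct, a setting chosen after seeing the data.

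In the stress list 18 of 24 members rose and 1 fell (18 and 3 adjusted over the list alone, adjusted p = 7.7e-16). They included the transcription factors ATF3 (log2 3.52 ± 0.15) and XBP1 (1.73 ± 0.12) and the asparagine synthetase ASNS (2.88 ± 0.23). In the interferon list 0 of 28 rose and 13 fell (0 and 15 over the list alone, adjusted p = 1e-06), with OAS3 at -1.89 ± 0.18 and CMPK2 at -1.38 ± 0.16. Senescence and secretory genes had 11 rises and 0 falls of 24 (13 and 2 over the list alone, adjusted p = 5.7e-06), among them the chemokine CXCL8 (3.63 ± 0.22) and the cyclin-dependent kinase inhibitor CDKN2B, from 38.9 ± 0.202 to 110 ± 9.65 CPM. ERK pathway output had 12 rises and 2 falls of 22 (12 and 2 over the list alone, adjusted p = 3.1e-06, and adjusted p = 0.079 with an estimated correlation). EGR1, an immediate early factor, rose from 0.207 ± 0.0492 to 4.27 ± 0.296 CPM, and HBEGF, an EGF receptor ligand, from 14.4 ± 0.568 to 83.5 ± 4.5 CPM. Cell cycle genes had 1 rise and 17 falls of 35 (1 and 19 over the list alone, adjusted p = 0.00014, and adjusted p = 0.11 with an estimated correlation), with the replication genes MCM4 at -0.66 ± 0.10 and PCNA at -0.70 ± 0.12.

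Sterol synthesis genes had 0 rises and 7 falls of 24 (1 and 8 over the list alone, adjusted p = 0.0042, and adjusted p = 0.14 with an estimated correlation), including the mevalonate kinase MVK (-1.23 ± 0.23). Neuroendocrine genes had 8 rises and 0 falls of 17 (8 and 0 over the list alone, adjusted p = 0.0063, and adjusted p = 0.066 with an estimated correlation), with the adhesion molecule NCAM1 at 3.06 ± 0.29 and a mean of 3.24 ± 0.166 CPM. The p53 target list had 10 rises and 2 falls of 30 (10 and 2 over the list alone, adjusted p = 0.0082, and adjusted p = 0.066 with an estimated correlation). Its members SESN2 (3.63 ± 0.31) and PMAIP1 (1.48 ± 0.16) are also known targets of the stress factor ATF4, and PC3 lacks p53. Reported PEA3 factor targets had 10 rises and 4 falls of 26 (10 and 4 over the list alone, adjusted p = 0.017, and adjusted p = 0.094 with an estimated correlation). Hypoxia and glycolysis genes had 2 rises and 8 falls of 26 (2 and 10 over the list alone, adjusted p = 0.016, and adjusted p = 0.22 with an estimated correlation). PC3 marker genes had 4 rises and 0 falls of 10 (4 and 1 over the list alone, adjusted p = 0.033, and adjusted p = 0.23 with an estimated correlation). The calls ended without single libraries: PEA3 factor targets without ETV4WT replicate 1 (0.11), hypoxia without ETV4WT replicate 2 (0.069), and PC3 markers without eGFP replicate 1 (0.054), eGFP replicate 2 (0.058) or ETV4WT replicate 1 (0.071). Without both replicate 2 construct libraries the adjusted p was 0.058 for hypoxia and 0.057 for PC3 markers.

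The other lists did not pass, in order of p. Epithelial genes had 2 rises and 9 falls of 28 (2 and 9 over the list alone, adjusted p = 0.055) and luminal genes 3 rises and 7 falls of 19 (4 and 8 over the list alone, adjusted p = 0.13). Ribosomal proteins had 0 rises and 0 falls of 34 (0 and 0 over the list alone, adjusted p = 0.29) and immune cell genes 1 rise and 0 falls of 6 (1 and 0 over the list alone, adjusted p = 0.43). NF-kB genes had 2 rises and 6 falls of 20 (3 and 7 over the list alone, adjusted p = 0.45) and TGF-beta genes 4 rises and 3 falls of 24 (5 and 3 over the list alone, adjusted p = 0.63). Immediate early and heat shock genes had 7 rises and 6 falls of 24 (7 and 8 over the list alone, adjusted p = 0.66) and 22Rv1 markers 3 rises and 3 falls of 10 (4 and 3 over the list alone, adjusted p = 0.69). Mesenchymal genes had 5 rises and 6 falls of 29 (5 and 7 over the list alone, adjusted p = 0.83) and basal genes 3 rises and 3 falls of 15 (3 and 4 over the list alone, adjusted p = 0.85). Stromal and endothelial genes had 2 rises and 3 falls of 16 (2 and 3 over the list alone, adjusted p = 0.87) and mitochondrial transcripts 0 rises and 1 fall of 13 (0 and 0 over the list alone, adjusted p = 0.95). The epithelial list passed without eGFP replicate 1 (0.023) or ETV4WT replicate 1 (0.014), and the ribosomal list without ETV4WT replicate 1 (0.018). For the mesenchymal, luminal and basal lists the mean was above 0 while the median and the test were negative. For the immediate early list the median alone was below 0, and for the 22Rv1 marker list the test alone was negative. Of genes high in 22Rv1, some had low counts in these libraries. PMEPA1 had 76 counts against 3 with eGFP (ratio 23.5, 95% interval 7.75 to 117; log2 change 3.45 without eGFP replicate 1 and 8.16 without eGFP replicate 2) and TMPRSS2 had 14 against 0 (at least 4.34-fold higher), while KLK3 stayed at 0 and FOLH1 stood at 0.0186 and 0.0201 CPM. Intervals and floors (3 counts over a group at 0) cover counting error alone.

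The count of 5434 fell to 2884 without eGFP replicate 1, 2549 without eGFP replicate 2 (72.5% higher) and 3297 without ETV4WT replicate 2, and was 4054 without both replicate 2 construct libraries of PC3. With upper-quartile scaling the log2 changes shifted by a median of 0.116, and 69.2% of the changed genes were higher against 54.4% with the main scaling. More genes were down than up without ETV4WT replicate 1 (3090 up and 3190 down) and with a floor of 1 CPM (2166 up and 2527 down), so the balance of directions is not settled.

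The second comparison asks what the mutated ETV4 changes in PC3. In the libraries labelled ETV4AAA, 4 of 10 PC3 marker genes rose and 0 fell (adjusted p = 4.5e-08), and 6 of 28 interferon response genes fell and 0 rose (adjusted p = 5.8e-07). The caveolin CAV2 rose from 39.3 ± 1.2 to 113 ± 7.29 CPM (log2 1.52 ± 0.18, adjusted p = 0.000587). OAS1 fell from 13.1 ± 0.0926 to 4.05 ± 0.223 CPM (log2 -1.69 ± 0.23, adjusted p = 0.00186). The adhesion gene CDH1, which encodes E-cadherin, fell by 1.20 ± 0.12 on the log2 scale (adjusted p = 0.000258). In all, 858 genes changed, 569 up and 289 down.

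MYL10 (log2 5.54 ± 0.26), PROKR1 (5.08 ± 0.25) and PDE2A (4.21 ± 0.27) were again among the largest rises, with the transglutaminase TGM2 (3.56 ± 0.30) and the hemidesmosome collagen COL17A1 (3.22 ± 0.28). LRRC15 reached 64.4 ± 6.09 CPM (9.95 ± 0.36, and 10.57 without eGFP replicate 2). Large falls included the serotonin receptor HTR2B (-2.67 ± 0.34), the protease inhibitor SLPI (-2.10 ± 0.19) and the aldehyde dehydrogenase ALDH3A1 (-2.77 ± 0.31). GDF15, a stress-induced cytokine, fell by 2.73 ± 0.38 on the log2 scale, to 1.10 ± 0.648 CPM, and its log2 change was -3.53 without ETV4AAA replicate 1. ETV4 (0.46 ± 0.33, adjusted p = 0.495), ETV1 (-0.10 ± 0.13, adjusted p = 0.718) and ETV5 (0.19 ± 0.12, adjusted p = 0.446) did not pass. ETV4's log2 change was -0.15 without ETV4AAA replicate 1, 0.86 without ETV4AAA replicate 2 and 0.88 without both replicate 2 construct libraries.

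PC3 markers had 4 rises and 0 falls of 10 (4 and 0 over the list alone, adjusted p = 4.5e-08). Interferon genes had 0 rises and 6 falls of 28 (0 and 8 over the list alone, adjusted p = 5.8e-07), with OAS3 at -1.16 ± 0.18. The stress list had 8 rises and 0 falls of 24 (11 and 0 over the list alone, adjusted p = 9e-06, and adjusted p = 0.11 with an estimated correlation), with ATF3 at 1.34 ± 0.15. ERK pathway output had 7 rises and 0 falls of 22 (9 and 0 over the list alone, adjusted p = 2.1e-05, and adjusted p = 0.092 with an estimated correlation), with HBEGF at 1.61 ± 0.15 and the ephrin receptor EPHA4 at 1.36 ± 0.17. Epithelial genes had 0 rises and 5 falls of 28 (1 and 8 over the list alone, adjusted p = 2.1e-05, and adjusted p = 0.15 with an estimated correlation), with the ETS factor ELF3 at -1.66 ± 0.25. Senescence and secretory genes had 5 rises and 1 fall of 24 (5 and 1 over the list alone, adjusted p = 0.0036, and adjusted p = 0.062 with an estimated correlation), with CXCL8 at 2.77 ± 0.21. Luminal genes had 1 rise and 2 falls of 19 (1 and 3 over the list alone, adjusted p = 0.042, and adjusted p = 0.19 with an estimated correlation), with the pioneer factor FOXA1 at -0.86 ± 0.12 and CD24 at -0.96 ± 0.14. Ribosomal protein genes had 0 rises and 0 falls of 34 (0 and 0 over the list alone, adjusted p = 0.028, and adjusted p = 0.77 with an estimated correlation, test negative). The senescence call ended without ETV4AAA replicate 1 (0.069). The luminal call ended without eGFP replicate 2 (0.063), ETV4AAA replicate 2 (0.11) or both replicate 2 construct libraries (0.13), and the ribosomal call likewise (0.063, 0.73 and 0.74) and with DESeq2 size factors (0.056).

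The other lists did not pass, in order of p. PEA3 factor targets had 4 rises and 1 fall of 26 (6 and 1 over the list alone, adjusted p = 0.057) and p53 targets 4 rises and 1 fall of 30 (6 and 1 over the list alone, adjusted p = 0.087). 22Rv1 markers had 0 rises and 1 fall of 10 (0 and 1 over the list alone, adjusted p = 0.22) and immediate early and heat shock genes 4 rises and 0 falls of 24 (5 and 1 over the list alone, adjusted p = 0.28). Immune cell genes had 1 rise and 0 falls of 6 (1 and 0 over the list alone, adjusted p = 0.28) and mesenchymal genes 1 rise and 3 falls of 29 (2 and 8 over the list alone, adjusted p = 0.33). Hypoxia genes had 0 rises and 1 fall of 26 (0 and 1 over the list alone, adjusted p = 0.4) and neuroendocrine genes 2 rises and 0 falls of 17 (2 and 0 over the list alone, adjusted p = 0.45). Sterol synthesis genes had 1 rise and 0 falls of 24 (1 and 0 over the list alone, adjusted p = 0.45) and stromal and endothelial genes 3 rises and 0 falls of 16 (4 and 1 over the list alone, adjusted p = 0.48). Basal genes had 2 rises and 0 falls of 15 (2 and 1 over the list alone, adjusted p = 0.49) and mitochondrial transcripts 0 rises and 0 falls of 13 (0 and 0 over the list alone, adjusted p = 0.51). Cell cycle genes had 0 rises and 0 falls of 35 (0 and 0 over the list alone, adjusted p = 0.76) and NF-kB genes 3 rises and 1 fall of 20 (3 and 4 over the list alone, adjusted p = 0.83). TGF-beta genes had 2 rises and 1 fall of 24 (2 and 2 over the list alone, adjusted p = 0.96). Without ETV4AAA replicate 2, PEA3 factor targets (0.0098), p53 targets (0.013) and immediate early genes (0.045) passed, and PEA3 factor targets (0.036) and p53 targets (0.0089) did so without both replicate 2 construct libraries. For the NF-kB, immediate early and stromal lists the test was positive while the median and mean were below 0. The median of the basal list and the mean of the cell cycle list were below 0 with a positive test. For the TGF-beta and 22Rv1 marker lists the mean was above 0 with a negative test, and the median of the last was 0.

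The count of 858 rested on single libraries: it was 210 without eGFP replicate 1, 233 without eGFP replicate 2, 2123 without ETV4AAA replicate 1 (675 up and 1448 down, so that most went down) and 383 without ETV4AAA replicate 2. Without both replicate 2 construct libraries it was 588.

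The third comparison sets ETV4AAA against ETV4WT in PC3. In the libraries labelled ETV4AAA, 17 of 24 stress list genes were lower than in those labelled ETV4WT and 1 was higher (adjusted p = 2.1e-13), and 9 of 35 cell cycle genes were higher and 0 lower (adjusted p = 6.3e-08). FAM111B, a protease gene expressed in S phase, was 57.6 ± 7.46 against 12.6 ± 0.877 CPM (log2 2.19 ± 0.14, adjusted p = 5.14e-06). DDIT3, which encodes the stress factor CHOP, was 18.5 ± 2.84 against 51.2 ± 4.26 CPM (log2 -1.47 ± 0.17, adjusted p = 0.000186). The count was 2550 genes, 848 higher and 1702 lower with ETV4AAA.

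The calcium-binding protein S100P was 0.168 ± 0.0335 CPM with ETV4AAA and 5.09 ± 0.187 CPM with ETV4WT (log2 -4.92 ± 0.27), and BEST1, a chloride channel (-3.73 ± 0.25), the complement protease MASP1 (-3.56 ± 0.23) and INHBE (-3.42 ± 0.26) were also lower. The transcription factor MYB (1.89 ± 0.16), the cytochrome CYP1B1 (1.56 ± 0.16), the peptide APLN (1.55 ± 0.19) and HSPA1A (2.02 ± 0.26) were higher. EGR1 was 0.123 ± 0.0288 against 4.27 ± 0.296 CPM (log2 -5.10 ± 0.26). ETV5 was lower by log2 -0.57 ± 0.12 (adjusted p = 0.0103), a call that ended without ETV4WT replicate 2 (-0.49) or without both replicate 2 construct libraries (-0.58). ETV4 (0.03 ± 0.33, adjusted p = 1) and ETV1 (0.07 ± 0.13, adjusted p = 0.811) did not pass, and ETV4's log2 change ranged from -0.58 without ETV4AAA replicate 1 to 0.57 without ETV4WT replicate 1.

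The stress list had 1 rise and 17 falls of 24 (1 and 17 over the list alone, adjusted p = 2.1e-13), with ATF3 at -2.18 ± 0.14 and the serine synthesis enzyme PSAT1 at -1.10 ± 0.13. Cell cycle genes had 9 rises and 0 falls of 35 (16 and 0 over the list alone, adjusted p = 6.3e-08), with PCNA at 0.74 ± 0.12 and RRM2, a ribonucleotide reductase subunit, at 0.69 ± 0.12. Senescence and secretory genes had 2 rises and 7 falls of 24 (3 and 9 over the list alone, adjusted p = 0.00057), with CDKN2B at -1.62 ± 0.13 and MMP10 at -1.75 ± 0.20. Neuroendocrine genes had 0 rises and 7 falls of 17 (0 and 7 over the list alone, adjusted p = 0.0047, and adjusted p = 0.062 with an estimated correlation), with SCG3 at -2.67 ± 0.33. ERK output had 1 rise and 6 falls of 22 (4 and 6 over the list alone, adjusted p = 0.0099, and adjusted p = 0.25 with an estimated correlation), with the phosphatase DUSP5 at -0.76 ± 0.12 and HBEGF at -0.93 ± 0.15. Sterol synthesis had 1 rise and 0 falls of 24 (1 and 0 over the list alone, adjusted p = 0.0024, and adjusted p = 0.13 with an estimated correlation). The interferon list had 3 rises and 0 falls of 28 (3 and 0 over the list alone, adjusted p = 0.02, and adjusted p = 0.09 with an estimated correlation), with CMPK2 at 1.22 ± 0.16. Hypoxia genes had 3 rises and 2 falls of 26 (7 and 2 over the list alone, adjusted p = 0.018, and adjusted p = 0.24 with an estimated correlation), with VEGFA, an angiogenic factor, at -1.02 ± 0.16 against the list's direction. The p53 targets had 3 rises and 7 falls of 30 (5 and 10 over the list alone, adjusted p = 0.049, and adjusted p = 0.13 with an estimated correlation), with BTG2 at -2.63 ± 0.21. Hypoxia did not pass without ETV4WT replicate 2 (0.23) or without both replicate 2 construct libraries (0.12), and p53 targets did not without ETV4WT replicate 1 (0.078), ETV4AAA replicate 2 (0.074) or both replicate 2 construct libraries (0.11).

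The other lists did not pass, in order of p. PEA3 factor targets had 1 rise and 5 falls of 26 (1 and 8 over the list alone, adjusted p = 0.1) and NF-kB genes 3 rises and 1 fall of 20 (4 and 1 over the list alone, adjusted p = 0.27). PC3 markers had 0 rises and 1 fall of 10 (1 and 1 over the list alone, adjusted p = 0.3) and basal genes 1 rise and 0 falls of 15 (0 and 0 over the list alone, adjusted p = 0.4). TGF-beta genes had 0 rises and 5 falls of 24 (0 and 6 over the list alone, adjusted p = 0.45) and stromal and endothelial genes 1 rise and 0 falls of 16 (3 and 0 over the list alone, adjusted p = 0.45). Epithelial genes had 1 rise and 3 falls of 28 (1 and 5 over the list alone, adjusted p = 0.58) and mesenchymal genes 3 rises and 4 falls of 29 (5 and 5 over the list alone, adjusted p = 0.68). Mitochondrial transcripts had 0 rises and 0 falls of 13 (0 and 0 over the list alone, adjusted p = 0.68) and luminal genes 2 rises and 3 falls of 19 (2 and 3 over the list alone, adjusted p = 0.72). 22Rv1 markers had 2 rises and 3 falls of 10 (2 and 4 over the list alone, adjusted p = 0.72) and immediate early and heat shock genes 5 rises and 4 falls of 24 (7 and 4 over the list alone, adjusted p = 0.85). Ribosomal proteins had 0 rises and 0 falls of 34 (0 and 0 over the list alone, adjusted p = 0.87) and immune cell genes 0 rises and 0 falls of 6 (1 and 1 over the list alone, adjusted p = 0.93). PEA3 factor targets passed without ETV4WT replicate 2 (0.042) and ribosomal genes without ETV4AAA replicate 1 (0.017). For the luminal and immediate early lists the mean alone was below 0. The median of the epithelial list was above 0 with a negative test, and for the stromal list the test was positive with a median and mean below 0. The list mean for basal genes was 0 on the log2 scale.

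The count was 1646 without ETV4AAA replicate 1, 1355 without both replicate 2 construct libraries (21% higher) and 959 with only the 4 libraries compared (66 higher and 893 lower, or 6.9% higher). With upper-quartile scaling 17% of the changed genes were higher, against 33.3% with the main scaling.

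**Figure D2:**
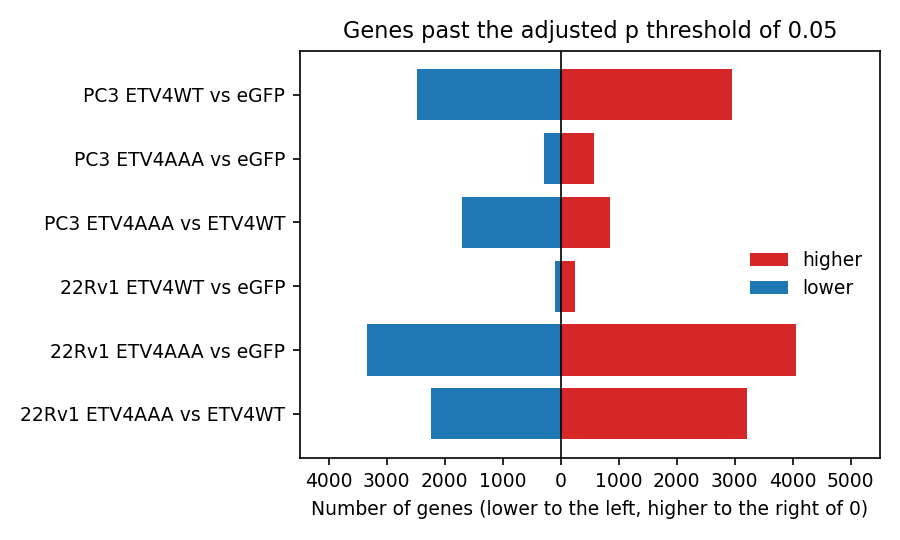
Number of genes that passed an adjusted p of 0.05 in each comparison, higher and lower, as bars from 0. The libraries labelled ETV4WT gave 5434 genes in PC3 and 348 in 22Rv1, and those labelled ETV4AAA 858 in PC3 and 7395 in 22Rv1.

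The fourth comparison asks what ETV4WT changes in 22Rv1, which expresses p53. Of 30 p53 targets 10 rose and 0 fell (adjusted p = 9.6e-22), and SPARC, a secreted matrix glycoprotein, went from 1 count over both eGFP libraries to 67.5 ± 3.31 CPM. CDKN1A, the cyclin-dependent kinase inhibitor p21 and a p53 target, rose from 64 ± 6.45 to 242 ± 0.858 CPM (log2 1.92 ± 0.16, adjusted p = 5.24e-05). DUSP4, a phosphatase that acts on ERK, rose from 7.52 ± 0.106 to 36.3 ± 2.06 CPM (log2 2.27 ± 0.12, adjusted p = 1.65e-06). Of the genes tested, 348 changed, 246 up and 102 down.

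The SPARC counts were 6402 against 1, a ratio of 6560 (95% interval 1180 to 259000). Its log2 change of 12.35 ± 0.28 became 14.64 without eGFP replicate 1 and 11.51 without eGFP replicate 2. With 1 count in the control this SE is too small, as the interval of the ratio shows. ETV4 rose by log2 3.95 ± 0.37, to 435 ± 70.3 CPM (adjusted p = 0.000156), while ETV1 fell by 1.05 ± 0.13 (adjusted p = 0.0017) and ETV5 fell by 1.24 ± 0.13 (adjusted p = 0.000413) on the log2 scale. Other large rises were the hormone subunit CGA (3.34 ± 0.25), the Wnt inhibitor WIF1 (3.28 ± 0.15), the cartilage collagen COL2A1 (3.23 ± 0.26), the calcium-binding protein TESC (3.20 ± 0.26) and RIPOR2 (3.12 ± 0.16). Albumin, ALB (-2.09 ± 0.23), the dehydrogenase DHRS2 (-1.96 ± 0.16), NIBAN1 (-1.83 ± 0.12), BEST1 (-1.76 ± 0.21) and the cystine transporter SLC7A11 (-1.44 ± 0.14) fell.

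The p53 target list had 10 rises and 0 falls of 30 (20 and 1 over the list alone, adjusted p = 9.6e-22), with the death receptor EDA2R at 1.65 ± 0.15 and the kinase PLK2 at 1.53 ± 0.15. Hypoxia and glycolysis genes had 5 rises and 0 falls of 26 (16 and 1 over the list alone, adjusted p = 1.7e-10). The glycolytic enzyme LDHA was 3120 ± 326 against 1920 ± 195 CPM (adjusted p = 0.0283), a call that ended without eGFP replicate 1 (log2 0.60), eGFP replicate 2 (0.81) or ETV4WT replicate 1 (0.58). Mesenchymal genes had 4 rises and 0 falls of 29 (4 and 0 over the list alone, adjusted p = 4.6e-10), with fibronectin, FN1, at 1.94 ± 0.13 and the transcription factor TWIST1 at 1.38 ± 0.12. Ribosomal protein genes had 2 rises and 0 falls of 34 (30 and 0 over the list alone, adjusted p = 1.3e-21, and adjusted p = 0.14 with an estimated correlation). They held 8.94% and 7.68% of the counts with ETV4WT against 6.31% and 5.92% with eGFP. The stress list had 0 rises and 5 falls of 24 (3 and 10 over the list alone, adjusted p = 0.00039, and adjusted p = 0.16 with an estimated correlation). Cell cycle genes had 0 rises and 0 falls of 35 (0 and 4 over the list alone, adjusted p = 0.00072, and adjusted p = 0.14 with an estimated correlation), with MCM7, a replication gene, at -0.28 ± 0.19 (adjusted p = 0.549).

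Basal genes had 2 rises and 0 falls of 15 (4 and 0 over the list alone, adjusted p = 0.018, and adjusted p = 0.28 with an estimated correlation), with the hyaluronan receptor CD44 at 1.02 ± 0.11. The 22Rv1 markers had 2 rises and 0 falls of 10 (4 and 3 over the list alone, adjusted p = 0.021, and adjusted p = 0.11 with an estimated correlation), with prostatic acid phosphatase, ACP3, at 1.36 ± 0.15. Mitochondrial transcripts had 0 rises and 0 falls of 13 (0 and 0 over the list alone, adjusted p = 0.032, and adjusted p = 0.55 with an estimated correlation, test positive). ERK output had 4 rises and 2 falls of 22 (5 and 7 over the list alone, adjusted p = 0.038, and adjusted p = 0.37 with an estimated correlation), with DUSP6 at 1.48 ± 0.12 and PHLDA1 at 1.73 ± 0.13. Without eGFP replicate 1 the calls of 22Rv1 markers (0.05), mitochondrial transcripts (0.22) and ERK output (0.3) ended. Without eGFP replicate 2 those of basal genes (0.24), 22Rv1 markers (0.1) and ERK output (0.15) did, and ERK output also ended without ETV4WT replicate 1 (0.061). Without ETV4WT replicate 2 the calls of basal genes (0.23), 22Rv1 markers (0.12), mitochondrial transcripts (0.074) and ERK output (0.55) ended.

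The other lists did not pass, in order of p. Neuroendocrine genes had 3 rises and 0 falls of 17 (4 and 1 over the list alone, adjusted p = 0.062) and PC3 markers 1 rise and 0 falls of 10 (2 and 0 over the list alone, adjusted p = 0.07). Sterol synthesis genes had 0 rises and 0 falls of 24 (0 and 0 over the list alone, adjusted p = 0.13) and NF-kB genes 0 rises and 0 falls of 20 (0 and 0 over the list alone, adjusted p = 0.25). TGF-beta genes had 1 rise and 0 falls of 24 (2 and 0 over the list alone, adjusted p = 0.29) and senescence and secretory genes 2 rises and 0 falls of 24 (3 and 3 over the list alone, adjusted p = 0.32). Luminal genes had 1 rise and 1 fall of 19 (2 and 1 over the list alone, adjusted p = 0.36) and PEA3 factor targets 1 rise and 0 falls of 26 (1 and 1 over the list alone, adjusted p = 0.43). Stromal and endothelial genes had 1 rise and 0 falls of 16 (1 and 0 over the list alone, adjusted p = 0.68) and immediate early and heat shock genes 1 rise and 0 falls of 24 (1 and 0 over the list alone, adjusted p = 0.76). Immune cell genes had 0 rises and 0 falls of 6 (0 and 0 over the list alone, adjusted p = 0.8) and epithelial genes 0 rises and 0 falls of 28 (0 and 0 over the list alone, adjusted p = 0.83). Interferon genes had 1 rise and 0 falls of 28 (1 and 0 over the list alone, adjusted p = 0.96). TGF-beta genes passed without eGFP replicate 1 (0.036), and PC3 markers without eGFP replicate 2 (0.031) or ETV4WT replicate 2 (0.02). The senescence list had a positive test with a median and mean below 0, and the interferon list a negative test with a median and mean above 0. The count of 348 was 118 without eGFP replicate 1, 128 without eGFP replicate 2 (80.5% higher) and 119 without ETV4WT replicate 1 (84.9%, against 70.7%).

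The fifth comparison asks what the mutated ETV4 changes in 22Rv1, where it gave the highest count of the 6 comparisons. Of 35 cell cycle genes 34 fell and 0 rose (adjusted p = 6.6e-19), and of 22 genes of the ERK output list 13 rose and 5 fell (adjusted p = 6e-14). DUSP6, an ERK phosphatase, rose from 13.5 ± 1.21 to 861 ± 17.7 CPM (log2 5.99 ± 0.14, adjusted p = 4.15e-10). RRM2 fell from 126 ± 9.79 to 38.2 ± 3.39 CPM (log2 -1.72 ± 0.13, adjusted p = 8.08e-07), and the prostate transporter SLC45A3 fell to 30.7 ± 1.95 CPM (log2 -1.92 ± 0.17, adjusted p = 3.71e-06). In all, 7395 genes changed, 4054 up and 3341 down.

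SPARC reached 2230 ± 3.81 CPM, 194293 counts against 1 (ratio 217000, 95% interval 38900 to 8560000). Its log2 change of 17.40 ± 0.28 was 19.69 without eGFP replicate 1 and 16.55 without eGFP replicate 2, so this SE is likewise too small. Several genes with 0 counts in both eGFP libraries rose far above them. MYL10 was at least 3010-fold higher (92.7 ± 0.518 CPM), the hair-follicle keratin KRT75 at least 2420-fold (74.5 ± 5.12 CPM), the neutrophil calcium-binding protein S100A9 at least 2220-fold (68.5 ± 2.79 CPM), the secreted glycoprotein PAEP at least 1100-fold (33.9 ± 1.63 CPM) and the salivary mucin MUC7 at least 653-fold (20.1 ± 0.908 CPM). ALB (-3.72 ± 0.25), DHRS2 (-3.20 ± 0.17) and the cadherin CDH6 (-2.78 ± 0.23) fell. ETV4 rose by log2 3.58 ± 0.37 (adjusted p = 1.52e-05), while ETV1 fell by 2.16 ± 0.14 (adjusted p = 2.85e-07) and ETV5 fell by 2.11 ± 0.14 (adjusted p = 3.27e-07).

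**Figure D3:**
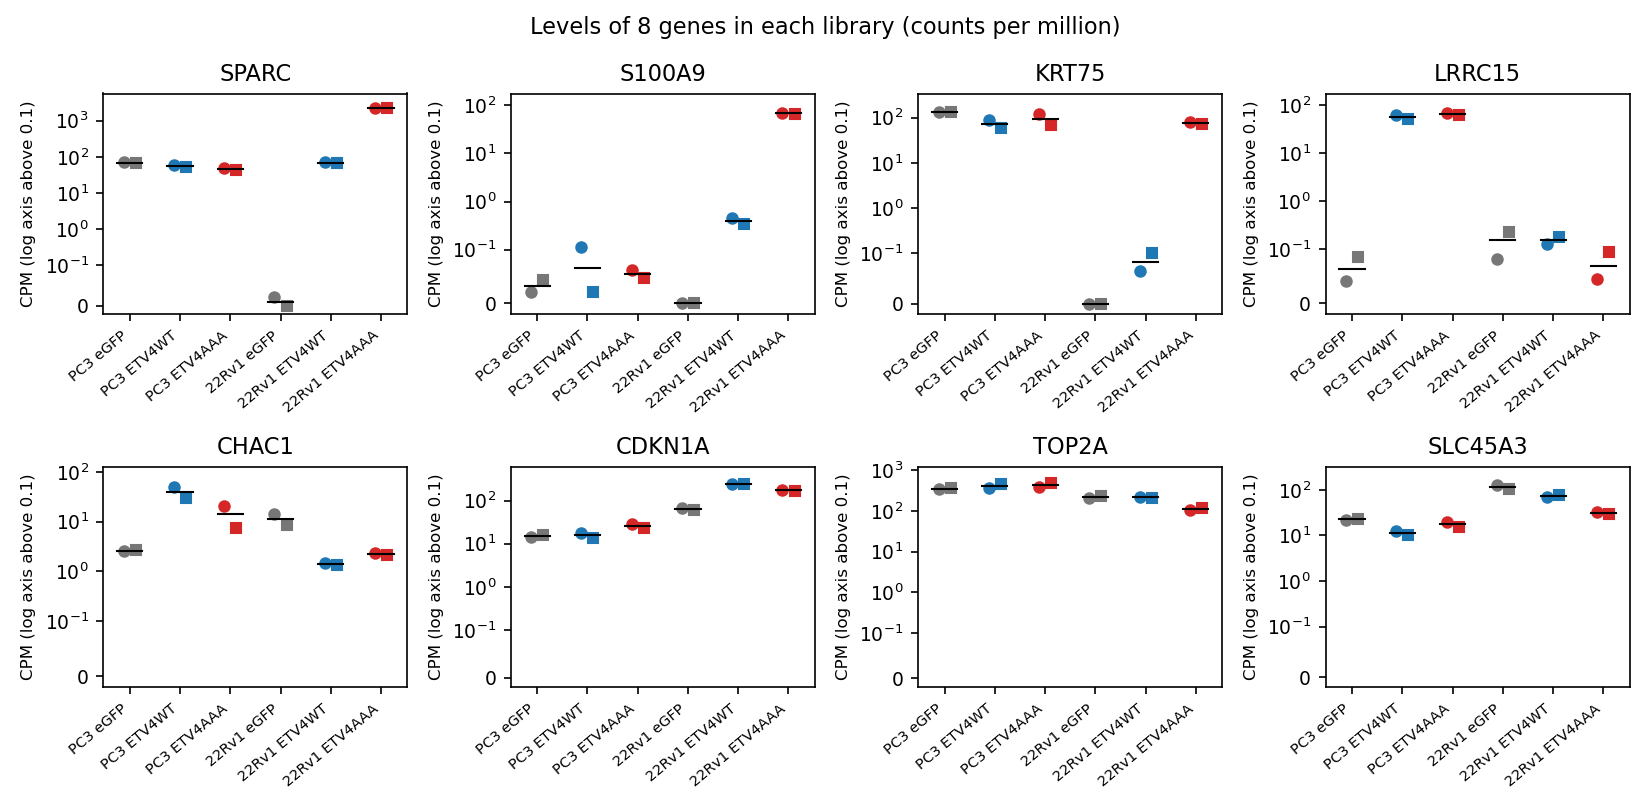
CPM (log axis above 0.1) of 8 genes in each of the 12 libraries, with points for libraries by cell line and construct. SPARC is near 0 in 22Rv1 eGFP, 67.5 with ETV4WT and 2230 with ETV4AAA, and SLC45A3 is lower in 22Rv1 with ETV4AAA (30.7) than with eGFP.

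Cell cycle genes had 0 rises and 34 falls of 35 (0 and 35 over the list alone, adjusted p = 6.6e-19), with a median log2 change of -1.20. ERK output had 13 rises and 5 falls of 22 (14 and 5 over the list alone, adjusted p = 6e-14). SPRY4 (5.36 ± 0.16) and DUSP4 (5.22 ± 0.13), both feedback inhibitors of ERK signalling, and PHLDA1 (4.99 ± 0.15) rose, and ETV1, ETV5, EGR1 (-1.84 ± 0.15), CCND1 and SPRED2, also an inhibitor of ERK signalling, fell. Mesenchymal genes had 17 rises and 0 falls of 29 (18 and 1 over the list alone, adjusted p = 1.4e-12), with TGFBI, a matrix protein induced by TGF-beta, at 9.07 ± 0.33 and FN1 at 3.57 ± 0.14. Senescence and secretory genes had 16 rises and 0 falls of 24 (17 and 0 over the list alone, adjusted p = 2.8e-12), with the growth factor binding proteins IGFBP3 (3.12 ± 0.12) and IGFBP5 (2.93 ± 0.19). Basal genes had 11 rises and 0 falls of 15 (11 and 0 over the list alone, adjusted p = 2.9e-12), with the laminin chain LAMB3 at 619 ± 114 against 3.65 ± 1.31 CPM, the integrin ITGA6 at 4.74 ± 0.16 and the neurotrophin receptor NGFR at 6.69 ± 0.36. Reported PEA3 factor targets had 17 rises and 2 falls of 26 (18 and 2 over the list alone, adjusted p = 7.9e-12), a median of 2.01, or 1.59 with groups at 0 set to the floor. Among them TWIST1 (4.43 ± 0.14), the morphogen BMP4 (4.60 ± 0.19) and the cyclooxygenase PTGS2 (5.11 ± 0.25) rose, and MET and MYC fell. CCND1, SPRED2, MET and MYC are named to complete the falls of their lists and were chosen after their values were seen. The p53 targets had 16 rises and 0 falls of 30 (17 and 0 over the list alone, adjusted p = 2.1e-05), with PLK2 at 6.52 ± 0.18 and GDF15 at 4.19 ± 0.35.

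Neuroendocrine genes had 9 rises and 3 falls of 17 (10 and 3 over the list alone, adjusted p = 3.1e-05), with the secretory granule protein SCG3 at 666 ± 55.3 against 67.1 ± 8.9 CPM and the Notch ligand DLL3 at 3.46 ± 0.20. PC3 markers had 8 rises and 1 fall of 10 (8 and 1 over the list alone, adjusted p = 5.4e-06), with CD44 at 1.79 ± 0.12. The 22Rv1 markers had 2 rises and 6 falls of 10 (2 and 6 over the list alone, adjusted p = 0.014, and adjusted p = 0.092 with an estimated correlation), with STEAP2 at -1.61 ± 0.16. Sterol synthesis genes had 2 rises and 7 falls of 24 (2 and 7 over the list alone, adjusted p = 0.016, and adjusted p = 0.2 with an estimated correlation), with the regulator INSIG1 at -0.78 ± 0.10. TGF-beta response genes had 11 rises and 3 falls of 24 (12 and 4 over the list alone, adjusted p = 0.00011, and adjusted p = 0.14 with an estimated correlation), with BAMBI, a decoy receptor, at 3.21 ± 0.18. NF-kB response genes had 8 rises and 1 fall of 20 (8 and 1 over the list alone, adjusted p = 0.0073, and adjusted p = 0.25 with an estimated correlation), with the inhibitor TNFAIP3 at 4.80 ± 0.21. Hypoxia genes had 13 rises and 1 fall of 26 (13 and 1 over the list alone, adjusted p = 0.0092, and adjusted p = 0.2 with an estimated correlation), with the peptide ADM at 2.78 ± 0.18. Stromal and endothelial genes had 6 rises and 2 falls of 16 (7 and 2 over the list alone, adjusted p = 0.0019), with the pericyte gene RGS5 at 4.38 ± 0.19 and the VEGF receptor KDR at least 150-fold higher. One of the falls was ENSG00000232995, a second Ensembl gene named RGS5 in GENCODE 29. The 22Rv1 marker call also ended without ETV4AAA replicate 2 (0.058).

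The other lists did not pass, in order of p. Stress genes had 5 rises and 9 falls of 24 (7 and 9 over the list alone, adjusted p = 0.14) and ribosomal proteins 2 rises and 0 falls of 34 (0 and 0 over the list alone, adjusted p = 0.4). Interferon genes had 10 rises and 4 falls of 28 (10 and 4 over the list alone, adjusted p = 0.46) and immune cell genes 1 rise and 1 fall of 6 (2 and 2 over the list alone, adjusted p = 0.65). Luminal genes had 3 rises and 5 falls of 19 (4 and 6 over the list alone, adjusted p = 0.68) and epithelial genes 3 rises and 4 falls of 28 (2 and 1 over the list alone, adjusted p = 0.81). Mitochondrial transcripts had 1 rise and 0 falls of 13 (0 and 0 over the list alone, adjusted p = 0.85) and immediate early and heat shock genes 10 rises and 6 falls of 24 (10 and 7 over the list alone, adjusted p = 0.99). For the epithelial and immediate early lists the test was negative with a median and mean above 0, and for the luminal list the mean alone was above 0. The count of 7395 was between 5169 and 5361 when 1 library was left out, and with upper-quartile scaling 3714 genes were up and 3821 down.

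The sixth comparison sets ETV4AAA against ETV4WT in 22Rv1, where ETV4 itself was 335 ± 76.9 and 435 ± 70.3 CPM (log2 -0.37 ± 0.33, adjusted p = 0.471). With ETV4AAA 34 of 35 cell cycle genes were lower and 0 higher (adjusted p = 2.9e-18), and of 22 genes of the ERK output list 13 were higher and 5 lower (adjusted p = 3.5e-16). DUSP6 was 861 ± 17.7 against 37.8 ± 0.619 CPM (log2 4.51 ± 0.13, adjusted p = 2.34e-09). MCM4 was 121 ± 1.25 against 254 ± 1.29 CPM (log2 -1.07 ± 0.10, adjusted p = 6.98e-06). The count was 5455 genes, 3219 higher and 2236 lower.

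PAEP was at least 1070-fold higher, the leukocyte receptor LILRB1 at least 333-fold (10.5 ± 0.652 CPM) and the actin-binding protein CORO2B at least 232-fold, all with 0 counts in ETV4WT. KRT75 was higher by log2 9.74 ± 0.43 and SPARC by 5.04 ± 0.15. The paraoxonase PON1 (-1.78 ± 0.17), the decarboxylase DDC (-1.71 ± 0.16), CFC1 (-1.82 ± 0.24) and the anion exchanger SLC26A3 (-1.67 ± 0.20) were lower. ETV1 fell by 1.11 ± 0.14 (adjusted p = 0.000107) and ETV5 fell by 0.86 ± 0.14 (adjusted p = 0.000757) on the log2 scale.

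Cell cycle genes had 0 rises and 34 falls of 35 (0 and 35 over the list alone, adjusted p = 2.9e-18), with PCNA at -1.18 ± 0.12 and the lamin LMNB1 at -1.08 ± 0.11. ERK output had 13 rises and 5 falls of 22 (14 and 5 over the list alone, adjusted p = 3.5e-16), with SPRY4 at 4.31 ± 0.15. PEA3 factor targets had 18 rises and 2 falls of 26 (19 and 2 over the list alone, adjusted p = 3.7e-14), with the chemokine receptor CXCR4 at 4.57 ± 0.24. Senescence and secretory genes had 15 rises and 1 fall of 24 (17 and 1 over the list alone, adjusted p = 1.8e-13). The EGF receptor ligand AREG was higher (5.61 ± 0.32), and the fall was that of CDKN1A, at 242 ± 0.858 CPM with ETV4WT and 178 and 172 CPM with ETV4AAA. Basal genes had 10 rises and 0 falls of 15 (11 and 0 over the list alone, adjusted p = 1e-12), with ITGA6 at 4.17 ± 0.16. Mesenchymal genes had 14 rises and 0 falls of 29 (15 and 0 over the list alone, adjusted p = 1.2e-09), with TGFBI at 8.30 ± 0.31. The 22Rv1 markers had 0 rises and 7 falls of 10 (0 and 7 over the list alone, adjusted p = 3.1e-05), with the kallikrein KLK2 at -0.98 ± 0.13. PC3 markers had 8 rises and 1 fall of 10 (8 and 1 over the list alone, adjusted p = 9e-06), with S100A6 at 2.16 ± 0.18.

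Neuroendocrine genes had 7 rises and 2 falls of 17 (8 and 3 over the list alone, adjusted p = 7e-05), with SCG3 at 3.37 ± 0.15. Stromal and endothelial genes had 7 rises and 1 fall of 16 (8 and 1 over the list alone, adjusted p = 0.00018), with the proteoglycan CSPG4 at 4.87 ± 0.31. TGF-beta response genes had 10 rises and 3 falls of 24 (11 and 3 over the list alone, adjusted p = 8.6e-05, and adjusted p = 0.14 with an estimated correlation), with the transcription factor BHLHE40 at 3.43 ± 0.18. Sterol synthesis had 0 rises and 11 falls of 24 (1 and 13 over the list alone, adjusted p = 0.00025, and adjusted p = 0.09 with an estimated correlation), with the farnesyltransferase FDFT1 at -0.75 ± 0.11. NF-kB response genes had 6 rises and 1 fall of 20 (6 and 1 over the list alone, adjusted p = 0.012, and adjusted p = 0.29 with an estimated correlation), with the adhesion molecule ICAM1 at 3.57 ± 0.26. Ribosomal protein genes had 0 rises and 4 falls of 34 (0 and 0 over the list alone, adjusted p = 0.0025, and adjusted p = 0.66 with an estimated correlation). The NF-kB call ended without ETV4WT replicate 1 (0.056) or ETV4AAA replicate 1 (0.059), and the ribosomal call without ETV4WT replicate 1 (0.056).

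The other lists did not pass, in order of p. Luminal genes had 2 rises and 4 falls of 19 (3 and 5 over the list alone, adjusted p = 0.32) and interferon genes 7 rises and 3 falls of 28 (8 and 4 over the list alone, adjusted p = 0.38). Mitochondrial transcripts had 0 rises and 0 falls of 13 (0 and 0 over the list alone, adjusted p = 0.54) and p53 targets 7 rises and 3 falls of 30 (7 and 3 over the list alone, adjusted p = 0.55). Immune cell genes had 2 rises and 1 fall of 6 (2 and 1 over the list alone, adjusted p = 0.68) and epithelial genes 1 rise and 1 fall of 28 (1 and 1 over the list alone, adjusted p = 0.68). Stress genes had 5 rises and 4 falls of 24 (6 and 6 over the list alone, adjusted p = 0.83) and hypoxia genes 5 rises and 5 falls of 26 (5 and 5 over the list alone, adjusted p = 0.85). Immediate early and heat shock genes had 6 rises and 5 falls of 24 (9 and 6 over the list alone, adjusted p = 0.88). The p53 list had a positive test and mean with a median below 0, and the epithelial and stress lists a mean above 0 with a negative test and median. For the immediate early list the median and mean were above 0 with a negative test, and the median of the immune list was 0. The count was 3415 without ETV4AAA replicate 1.

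**Figure D4:**
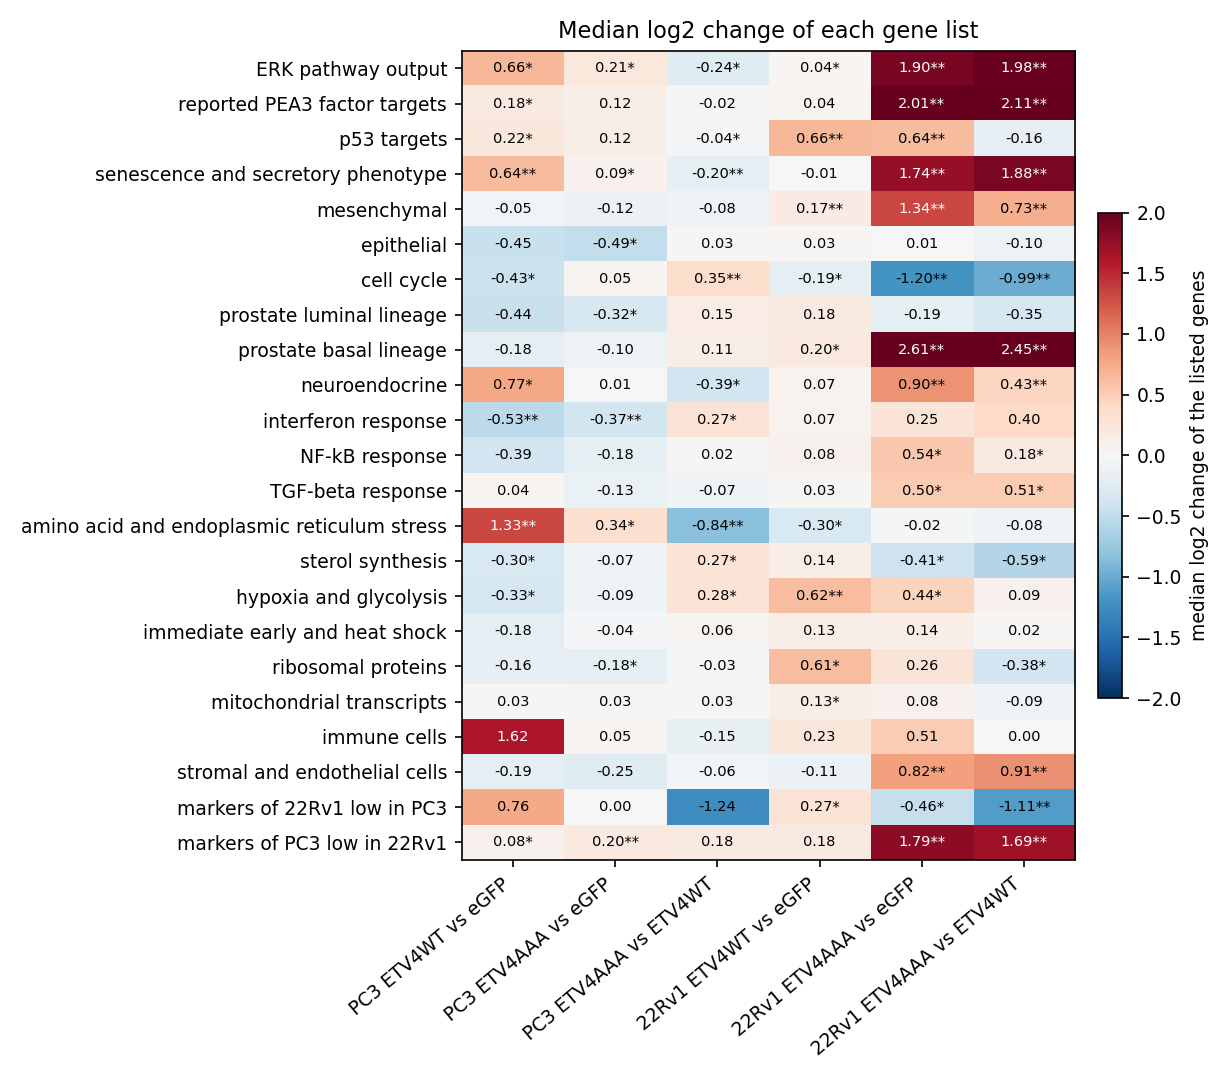
Median log2 change of 23 gene lists (vertical axis) in the 6 comparisons (horizontal axis), as colour, with 1 star for an adjusted p under 0.05 and a second where an estimated correlation also gives one. The cell cycle list has its lowest median with ETV4AAA against eGFP in 22Rv1 (-1.20), and the stress list its highest with ETV4WT in PC3 (1.33).

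The effects of a construct were then compared between the lines, as 22Rv1 against PC3. The ETV4WT effect differed for 2903 genes, the ETV4AAA effect for 3766 and the ETV4AAA against ETV4WT effect for 4872. CHAC1 rose in PC3 and fell in 22Rv1 with ETV4WT (log2 3.93 and -3.00, difference -6.93 ± 0.63, adjusted p = 4.11e-05), though its fall in 22Rv1 did not pass when either ETV4WT library was left out (-3.05 and -2.95). FAM111B was higher with ETV4AAA than ETV4WT in PC3 and lower in 22Rv1 (2.19 and -1.17, difference -3.35 ± 0.19, adjusted p = 3.16e-07). With ETV4WT the stress list was lower in 22Rv1 than in PC3 (2 members higher, 16 lower of 24, adjusted p = 2e-22) and hypoxia genes were higher (14 and 2 of 26, adjusted p = 1e-08). With ETV4AAA, cell cycle genes were lower in 22Rv1 (0 and 29 of 35, adjusted p = 2e-22), and ERK output (10 and 5 of 22, adjusted p = 3.5e-16), mesenchymal genes (13 and 1 of 29, adjusted p = 3.8e-16) and basal genes (9 and 0 of 15, adjusted p = 1.8e-12) were higher. For ETV4AAA against ETV4WT the cell cycle (0 and 33 of 35, adjusted p = 3.2e-26), ERK output (14 and 2 of 22, adjusted p = 2.2e-22) and senescence lists (17 and 1 of 24, adjusted p = 2.2e-14) differed most. These list calls held with an estimated correlation. The count of 2903 was 1547 without PC3 eGFP replicate 1, 1483 without PC3 eGFP replicate 2, 4362 without PC3 ETV4WT replicate 1, 1858 without PC3 ETV4WT replicate 2, 1628 without 22Rv1 eGFP replicate 2 and 1789 without 22Rv1 ETV4WT replicate 1. The count of 3766 was 2412 without PC3 eGFP replicate 1 and 2330 without PC3 eGFP replicate 2.

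Within PC3, 474 genes were higher and 228 lower with both constructs, against 72.4 and 30.8 if the calls were independent, and 8 went opposite ways against 97.4. Within 22Rv1 these were 223 and 79, against 42.9 and 14.7, with 9 opposite against 53.2. Each pair of comparisons shares its 2 eGFP libraries, and a split would leave 1 for each, so part of the excess may come from the shared control. In 20 simulations with no change and a shared control, the shared calls averaged 0.05 in PC3 and 0 in 22Rv1. Few genes pass where none is changed, so this number cannot show how many of the observed shared calls come from the shared control. The covariance of log2 changes over 13573 genes was 0.288 in PC3 and 0.308 in 22Rv1, against a simulated 0.026, and Pearson's r across genes was 0.62 and 0.57, against a simulated 0.5. Genes are not independent replicates. The PC3 overlap of 702 was 192 without eGFP replicate 1, 208 without eGFP replicate 2, 1187 without ETV4AAA replicate 1 and 349 without ETV4AAA replicate 2. The 22Rv1 overlap of 302 was 106 without eGFP replicate 1, 117 without eGFP replicate 2 and 113 without ETV4WT replicate 1.

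Across lines the ETV4WT effect shared 61 higher genes against 31.3 and 16 lower against 10.9 (one-sided Fisher's exact p = 1.7e-07 and 0.0736). Opposite were 66 against 39.2. The ETV4AAA effect shared 262 higher genes against 99.3 (Fisher's exact p = 1.4e-57) and 59 lower against 41.6 (p = 0.00306), with 138 opposite against 132.2. The difference between the constructs shared 143 higher genes against 117.5 (Fisher's exact p = 0.00658) and 153 lower against 163.8 (p = 0.832), with 645 opposite against 317.4. Of the opposite calls for ETV4WT, 38 were higher in PC3 and lower in 22Rv1 against 13 (one-sided Fisher's exact p = 2.66e-10), and 28 the reverse against 26.2 (p = 0.385). For the difference between the constructs these were 225 against 81.6 (Fisher's exact p = 1.76e-47) and 420 against 235.8 (p = 1.45e-35), and for ETV4AAA 53 against 81.8 (p = 1) and 85 against 50.4 (p = 3.32e-07). These p-values, post hoc for opposite calls, take genes, some low in 1 line, as independent. They do not measure how far effects are shared. Pearson's r across lines was -0.03, 0.11 and -0.09 for ETV4WT, ETV4AAA and their difference. LRRC15 rose with both constructs in PC3 and was under 0.3 CPM in 22Rv1.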

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

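The tests of explanations in this part were chosen after the results were seen, and those of differences between lines were planned. The tests for myeloid and endothelial cells and PC3 cells were also revised after their first values were seen. Differences below are those of edgeR's interaction contrast, 22Rv1 minus PC3, as log2 ± SE with Benjamini-Hochberg adjusted p and n = 2 libraries per group. For genes with 0 to 3 counts in a group, SPARC among them, they depend on the prior count, and their SE can be too small. ETV4 was not above eGFP in replicate 2 of either PC3 construct.

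Construct effects differed between the lines for 2903 genes (ETV4WT), 3766 (ETV4AAA) and 4872 (ETV4AAA against ETV4WT).

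For ETV4WT the effect was higher in 22Rv1 for SPARC (12.67 ± 0.32, adjusted p = 1.93e-09), FAIM2 (6.31 ± 0.79, 0.000306), RIPOR2 (5.90 ± 0.24, 2.42e-07), HR (4.50 ± 0.66, 0.000942) and HAPLN1 (4.35 ± 0.70, 0.0018). SPARC was 14.96 and 11.83 without 22Rv1 eGFP replicates 1 and 2, FAIM2 8.52 and 5.52 without PC3 ETV4WT replicates 1 and 2, HR 5.23 without PC3 ETV4WT replicate 1 and 3.91 without 22Rv1 ETV4WT replicate 2, and HAPLN1 3.50 and 6.64 without 22Rv1 eGFP replicates 1 and 2. It was lower in 22Rv1 for LRRC15 (-9.71 ± 0.74, 1.93e-05), CHAC1 (-6.93 ± 0.63, 4.11e-05), LPL (-6.77 ± 1.08, 0.0023), NLRP3 (-6.31 ± 1.49, 0.0195) and NKILA (-6.22 ± 1.12, 0.00465). LRRC15 was -10.41 without PC3 eGFP replicate 2 and -8.82 without 22Rv1 eGFP replicate 2. NLRP3 did not pass without 22Rv1 eGFP replicate 2 (-5.08), ETV4WT replicate 1 (-6.33) or ETV4WT replicate 2 (-6.30), and was -6.96 without eGFP replicate 1.

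For ETV4AAA the effect was higher in 22Rv1 for SPARC (18.00 ± 0.31, 2.04e-11), KRT75 (15.29 ± 0.71, 1.68e-07), S100A9 (13.89 ± 1.84, 0.000423), TGM5 (12.13 ± 3.08, 0.0238) and FOXJ1 (11.98 ± 2.43, 0.00638). SPARC was 20.29 and 17.16 without 22Rv1 eGFP replicates 1 and 2. Without PC3 eGFP replicate 2 TGM5 (9.84) and FOXJ1 (8.84) did not pass, and without replicate 1 they were 13.01 and 12.93. It was lower in 22Rv1 for LRRC15 (-11.08 ± 0.79, 2e-06), SCEL (-6.14 ± 1.88, 0.0486), CHAC1 (-4.80 ± 0.61, 0.000206), JAKMIP1 (-4.77 ± 1.15, 0.0196) and SYT4 (-4.36 ± 0.81, 0.00303). LRRC15 was -11.69 without PC3 eGFP replicate 2, -10.20 without 22Rv1 eGFP replicate 2 and -11.69 without 22Rv1 ETV4AAA replicate 2, and CHAC1 was -3.88 without PC3 ETV4AAA replicate 1. SCEL did not pass without PC3 eGFP replicate 1 (-6.16) or 2 (-6.15), PC3 ETV4AAA replicate 2 (-5.96), 22Rv1 eGFP replicate 2 (-2.09) or 22Rv1 ETV4AAA replicate 1 or 2 (both -6.15), and was -7.09 without 22Rv1 eGFP replicate 1. JAKMIP1 did not pass without 22Rv1 eGFP replicate 1 (-4.20) or ETV4AAA replicate 1 or 2 (both -4.78), and SYT4 was -6.67 and -3.56 without PC3 eGFP replicates 1 and 2. SCEL and JAKMIP1 were 0 CPM with ETV4AAA in 22Rv1.

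For ETV4AAA against ETV4WT the effect was higher in 22Rv1 for PAEP (15.68 ± 0.68, 8.23e-07), CORO2B (13 ± 1.06, 1.73e-05), GABRR1 (11.97 ± 2.06, 0.00243), CLEC1A (11.84 ± 0.85, 3.55e-06) and LILRB1 (11.23 ± 1.93, 0.00243). CORO2B was 12.25 without PC3 ETV4WT replicate 1, and GABRR1 was 11.38 without PC3 ETV4WT replicate 2 and 12.98 and 11.35 without 22Rv1 ETV4WT replicates 1 and 2. CLEC1A was 10.90 and 14.16 without PC3 ETV4AAA replicates 1 and 2 and 11.06 and 14.15 without 22Rv1 ETV4WT replicates 1 and 2. LILRB1 was 12.21 without PC3 ETV4WT replicate 1 and did not pass without replicate 2 (7.25). The effect was lower in 22Rv1 for CDH7 (-3.42 ± 0.30, 8.06e-06), FAM111B (-3.35 ± 0.19, 3.16e-07), DTX4 (-2.65 ± 0.29, 4.27e-05) and PRR15L (-2.63 ± 0.29, 4.92e-05).

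More genes passed with ETV4WT than ETV4AAA in PC3 (5434 and 858) and fewer in 22Rv1 (348 and 7395). With the replicate variance subtracted, the SD of log2 changes was larger for the construct with more calls by 1.71 times in PC3 (0.616 and 0.36) and 3.37 times in 22Rv1 (0.894 and 0.265), which argues against replicate spread alone. ETV4 mRNA differed between ETV4AAA and ETV4WT by log2 -0.37 in 22Rv1 and 0.03 in PC3, within 2 SE of 0, so its part stays open. If the PC3 labels are exchanged, the construct difference correlated across the lines with r = 0.086 (jackknife SE 0.014). As labelled, 645 calls for it were opposite across lines (317.4 if independent) and 296 shared. A label exchange stays open. A biological difference between the lines was not tested apart from these.

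Some genes known from blood or vessel cells were higher in the 22Rv1 ETV4AAA libraries than with eGFP, although the sort kept eGFP-positive, DAPI-negative cells. They were 7 members of the immune and the stromal and endothelial lists, with S100A9 and LILRB1 added after their values were seen. The immune list did not pass (adjusted p = 0.65). The other myeloid markers had a median of 0.212 CPM, 0.31% of S100A9 at 68.5 CPM (0.254% to 0.365% with any 1 marker left out; S100A8 2.58, LYZ 0.174, TYROBP 0 and PTPRC 0.0119 CPM), which argues against myeloid cells. Of 9 such genes 77.8% lay over 2 SD above PC3 eGFP (RGS5 80.7 against 2.6 CPM), arguing against PC3 cells or RNA for these. PDGFRA (0.534 against 25.5) and PECAM1 (0.689 against 13 CPM) lay below, so a trace of PC3 RNA stays open. The other endothelial markers had a median of 9.3% of KDR at 4.62 CPM (1.78% to 16.8%; VWF 0.0475, CDH5 0.034, EGFL7 5.87 and TIE1 2.71 CPM), so endothelial cells cannot be told apart from expression by the 22Rv1 cells. That 22Rv1 cells themselves express S100A9 with ETV4AAA is a hypothesis and was not tested apart from these.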

How the results depend on the processing

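The floor of 1 CPM within the line and leaving out both PC3 replicate 2 construct libraries were chosen after seeing the data. The counts of changed genes in the 6 comparisons within lines, the 3 differences between lines and the overlaps stayed within 1.5 times their main values under DESeq2 size factors, upper-quartile factors, the DESeq2 Wald test, limma-voom, the replicate block and, within lines, the floor of 1 CPM. No named gene that passed the threshold, and no list that did, changed direction under any alternative run, while ETV4 in PC3, which did not pass, changed sign without replicate 1 of a construct (ETV4WT against eGFP 0.43 to -0.12, ETV4AAA against eGFP 0.46 to -0.15, ETV4AAA against ETV4WT 0.03 to -0.58 without ETV4AAA replicate 1), as did other genes that did not pass. For the values below that moved, the cause was not tested, except that fewer genes pass 2 thresholds than 1.

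With the added 2-fold threshold the changed genes were 2972 for ETV4WT, 479 for ETV4AAA and 1474 for ETV4AAA against ETV4WT in PC3, and 221, 4280 and 2956 in 22Rv1. The overlaps were then 379 in PC3, 194 in 22Rv1, and 34, 145 and 58 across lines for the same contrasts in order. With no low-count filter the changed genes were 2152 for ETV4AAA in PC3 (907 higher and 1245 lower) and 904 for ETV4WT in 22Rv1, the ETV4WT difference between lines 4436, and the overlaps 1729 in PC3, 692 in 22Rv1, 135 for ETV4WT across lines and 568 for ETV4AAA across lines. With each line fitted on its own ETV4AAA gave 466 genes in PC3 and ETV4AAA against ETV4WT 1657, and the overlaps were 425 in PC3, 174 for ETV4AAA across lines and 194 for ETV4AAA against ETV4WT across lines. With only the 4 libraries compared these were 362, 959, 335, 133 and 96, ETV4WT gave 636 genes in 22Rv1, and the 22Rv1 overlap was 520. Without both PC3 replicate 2 libraries of a construct, ETV4AAA against ETV4WT gave 1355 genes in PC3 and an overlap of 149 across lines, while ETV4WT gave 4054 and ETV4AAA 588. Of the list tests, 70 passed and 32 did so with an estimated correlation.

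With 1 library left out, the changed genes ranged from 2549 to 6280 for ETV4WT, 210 to 2123 for ETV4AAA and 1646 to 1886 for ETV4AAA against ETV4WT in PC3, and from 118 to 263, 5169 to 5361 and 3415 to 4041 in 22Rv1. The differences between lines ranged from 1483 (22.2% higher) to 4362 (2278 higher and 2084 lower at the last, against 39.4% higher of 2903), 2330 to 4648 and 3488 to 4542. The overlaps ranged from 192 to 1187 in PC3 and 106 to 292 in 22Rv1, and from 22 to 66, 92 to 418 and 188 to 223 across lines. The list calls ranged from 66 to 70. The overlap of 77 genes for ETV4WT across lines was 49 without PC3 eGFP replicate 1, 22 without 22Rv1 eGFP replicate 1, 28 without 22Rv1 eGFP replicate 2, 27 without 22Rv1 ETV4WT replicate 1 and 43 without 22Rv1 ETV4WT replicate 2. That of 321 for ETV4AAA was 92 and 109 without PC3 eGFP replicates 1 and 2 and 174 without PC3 ETV4AAA replicate 2. That of 296 for ETV4AAA against ETV4WT was 188 and 194 without PC3 ETV4AAA replicates 1 and 2 and 192 without 22Rv1 ETV4AAA replicate 1.

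Upper-quartile factors shifted the log2 changes of ETV4WT in PC3 by a median of 0.116, where 3724 genes were then higher and 1661 lower. The ETV4WT difference between lines then had a median of -0.156 against 0.024, and the ETV4AAA difference -0.058 against 0.043. With the floor of 1 CPM, 46.2% of 4693 changed genes were higher with ETV4WT in PC3, against 54.4% of 5434, and ETV4AAA against ETV4WT gave 2099 genes in PC3, 44.8% of them higher. The other counts with this floor were 894 for ETV4AAA in PC3 and 436, 6039 and 4702 in 22Rv1.

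With the replicate block the counts were 6296 (3010 higher and 3286 lower), 868 and 2517 in PC3, 351, 7421 and 5503 in 22Rv1, and 3658 (1865 higher and 1793 lower in 22Rv1), 4066 and 4900 for the differences between lines, and 64 list tests passed. Among the reported lists, those on the other side of the threshold with the block were PEA3 factor targets (adjusted p = 0.08), PC3 markers (0.16) and epithelial genes (0.04, passed) for ETV4WT in PC3, luminal genes for ETV4AAA (0.059) and p53 targets for ETV4AAA against ETV4WT (0.18) in PC3, and ERK output (0.55) and 22Rv1 markers (0.11) for ETV4WT in 22Rv1. The replicate differences of PC3 ETV4WT and ETV4AAA correlated (r = 0.84 over 13573 genes), while those of eGFP ran against both (-0.30 and -0.29). In 22Rv1 the values were -0.33, 0.58 and -0.44 for eGFP with ETV4WT, eGFP with ETV4AAA and ETV4WT with ETV4AAA. What the replicate numbers share was not given. A block shared with eGFP does not test pairing of the PC3 constructs.

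Of 647 values for named genes, the side of the threshold was kept by 636 with DESeq2 size factors, 627 with upper-quartile factors, 634 with limma-voom and 626 with the DESeq2 Wald test, where 12 dropped below it, 5 rose past it and 4 had no value. With each line fitted on its own 40 dropped below the threshold and 11 rose past it, and with only the 4 libraries compared 59 and 12. When 1 library was left out, 2431 values kept their side, 270 dropped below it and 7 rose past it. Of 144 list tests, 141 kept their side with DESeq2 size factors and 124 with fry, where 5 dropped and 15 were gained. Genes under 1 CPM rest on fewer than 51.2 counts per library before scaling.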
